A study of Mus musculus with 4 samples.

How the data were processed

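RNA sequencing was carried out on LSK cells from mouse bone marrow, the lineage-negative fraction that carries Sca-1 and Kit and holds the stem cells and multipotent progenitors of the blood. Per the labels, RNA of sorted cells was made into libraries with an Illumina TruSeq RNA kit. The series holds 4 libraries in 2 groups, 2 labelled Hhex-deleted and 2 labelled wild-type. Each library was placed in its group by its title, which also gives its replicate number.

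The authors deposited a table of raw read counts per Entrez gene for all 4 libraries, and for each library a table of log2 RPKM values (log2 of reads scaled to gene length and to the library's total). The submitters' processing notes name Subread, featureCounts, limma and the mouse build mm9, without versions or roles. Strand setting, treatment of reads that match several genes, and filters are not given in the sources used here. The count table holds 26286 genes, of which 6804 had no read in any library. The deposited log2 RPKM tables hold 12662 genes. After gene length was added back, the sorted values of the deposited log2 RPKM tables differed between libraries by a median of 0.00078, so these values had also been brought to one distribution, a step that no label or header records. The counts, which carry depth, were therefore used for the main results, and the log2 RPKM values for one alternative.

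Gene symbols came from the deposited log2 RPKM tables and, for the other identifiers, from a RefSeq gene table of the mouse assembly GRCm38. A total of 18 symbols in them had been turned into dates and were replaced by their RefSeq symbols. A symbol was found for 24255 identifiers. The other 2031 identifiers, which held 2.99% of the counts, stayed in library totals and tests. The reference differs in build from the authors', so it served only for names, chromosome membership and the order of neighbouring genes, and no coordinates are given.

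Total counts per library were 29501591 and 29372938 in the libraries labelled Hhex-deleted and 27871827 and 28584399 in the wild-type libraries. CPM values are counts scaled by the library total of the tested genes times its TMM factor. On that scale a floor of 3 counts corresponded to 0.0995 to 0.109 CPM. A chi-square comparison of counts per gene gave values of 30.22 or more per degree of freedom for every pair of libraries, so no pair of libraries differed by sampling noise alone.

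Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr by group, whose defaults are a minimum count of 10 and a minimum total of 15, which left 14912 genes. Libraries were scaled by TMM factors. A quasi-likelihood model with group as its single term and robust dispersion was fitted to all 4 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 16.3%. Log2 fold changes are libraries labelled Hhex-deleted over wild-type, fitted with a prior count of 0.125. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, an approximation. For genes with 1 to 3 wild-type counts over both libraries, the ratio of pooled CPM is given with an exact conditional binomial interval of 95%. Where wild-type libraries held no count, a lower bound against 3 counts over the group is given. These intervals and floors cover counting error only.

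A total of 27 gene lists was written before the data were examined. Of their entries, 602 matched a current symbol, 2 an older symbol and 4 a symbol of the deposited tables, and 2 globin entries were not matched. For 26 lists, members were compared with all other tested genes by camera in limma 3.58.1 on voom log2 CPM, with the preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The list of sex-linked marker genes was used only to compare libraries. Genes are named by a rule also set before the data were examined. It takes Hhex and the cyclin-dependent kinase inhibitors, then the 10 largest fold changes in each direction among genes past the threshold with a mean of at least 1 CPM and groups that do not overlap. It also takes up to 4 members of each list by unadjusted p, and the measured neighbours of Hhex. The lists with a camera call or at least 3 members past the test were given 4 members and the others 2, a split made after the values were seen. Some genes that this rule selects are not reported here.

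The tests were tried on simulated counts of 14912 genes, for labelled Hhex-deleted against wild-type with 2 libraries each. edgeR recovered 71% of 100 genes changed 2-fold and 87% of 100 genes changed 4-fold, with 16 false calls, and made 10 calls when no gene was changed. DESeq2 1.42.0 recovered 73% and 82%, with 32 false calls and 21 calls when no gene was changed. limma-voom recovered 66% and 80%, with 11 false calls and 9 calls when no gene was changed. In a simulation that shifted the list of G2 and M phase genes by 0.5 on the log2 scale, camera with the preset correlation found that list and 2 of the other lists, and with no shift it called 1 of 26 lists. Each gene was simulated independently, while in the data the estimated correlation within a list reached 0.83 (oxidative phosphorylation genes). These simulated calls therefore do not give camera's rate of false calls for the lists in the data.

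Alternatives fixed before the data were examined were DESeq2, limma-voom, DESeq2 size factors in edgeR, library totals without TMM, no low-count filter, a stricter filter (at least 1 CPM in at least 2 libraries and a mean of at least 5 CPM, here without TMM factors), the replicate number as a block, a fit without robust dispersion, libraries thinned to the smallest total, and each library left out in turn. After seeing the data, limma on the deposited log2 RPKM values and a fit without genes of the X and Y chromosomes were added. With 2 libraries per group, other splits of the libraries were too few for a test of chance.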

Results

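The series profiled RNA of LSK cells from mouse bone marrow and compared 2 libraries labelled Hhex-deleted with 2 wild-type libraries. Hhex is a homeobox transcription factor, and the series title concerns its role in stem cell self-renewal through Cdkn2a. Total counts per library lay between 27871827 and 29501591. Nothing in the labels says whether the libraries came from separate mice, so p-values measure only the spread between these libraries. Labelled Hhex-deleted replicate 1 had 2662 CPM of Xist, the transcript that silences one X chromosome in females, against 2.59 CPM in labelled Hhex-deleted replicate 2 and 2.28 ± 0.546 CPM (SD, n = 2) in the wild-type libraries. The Y-linked gene Ddx3y stood at 0.34 CPM in that library, 138 CPM in the other library labelled Hhex-deleted and 129 ± 7.61 CPM (SD, n = 2) in wild-type. Eif2s3y, Kdm5d and Uty, also on the Y chromosome, had 0.07, 0.1 and 0.14 CPM in that library. That library therefore differs from the other libraries in sex markers, and counts for the lists that camera called are also given without it.

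The first comparison was of the targeted gene. Hhex itself had more reads in the libraries labelled Hhex-deleted, with 179 and 188 CPM against 127 and 115 CPM in wild-type. The means were 183 ± 6.06 and 121 ± 8.62 CPM (SD, n = 2 each). The log2 fold change was 0.60 ± 0.09 (SE), with an edgeR adjusted p of 0.0271. Gene-level counts include exons outside a deleted part, so this value does not check the deletion, and directions below refer to libraries as labelled. None of the 7 measured genes near Hhex passed the test, and their log2 fold changes ran from -0.11 for Myof to 0.09 for Btaf1, with Ide at -0.02, Kif11 at -0.07, Exoc6 at -0.04, Marchf5 at 0.07 and Cpeb3 at 0.02. For these neighbours 0 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The Hhex call was lost without wild-type replicate 1 (adjusted p = 0.0575) and without wild-type replicate 2 (adjusted p = 0.148).

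Of the 8 cyclin-dependent kinase inhibitors, 2 rose, both adjusted over all genes and adjusted over the list alone, and none fell. Cdkn2a, which encodes an inhibitor of the kinases that drive entry into S phase and, from another reading frame, ARF, had 30 and 27 reads in the libraries labelled Hhex-deleted and 1 and 2 reads in wild-type. The ratio of pooled CPM was 17.9 (95% interval 5.83 to 89.5), with a fitted log2 fold change of 4.06 ± 0.55 (SE) and an edgeR adjusted p of 0.0239. Its neighbour Cdkn2b, a related inhibitor, had 18 and 23 reads against 1 and 0, a ratio of 38.7 (95% interval 6.56 to 1560, edgeR adjusted p = 0.04). The count of Cdkn2a does not separate its reading frames. The other members did not pass the test: log2 fold changes were 0.14 for Cdkn1b, 0.19 for Cdkn2c, 0.09 for Cdkn2d, -0.1 for Cdkn3, -0.84 for Cdkn1c and -0.56 for Cdkn1a, which differed between wild-type libraries (56.1 and 15.7 CPM). With a library left out they ran from 0.01 (without wild-type replicate 2) to 0.3 (without wild-type replicate 1) for Cdkn1b, from 0.05 (without labelled Hhex-deleted replicate 2 or wild-type replicate 1) to 0.36 (without wild-type replicate 2) for Cdkn2c, from -0.17 (without labelled Hhex-deleted replicate 1) to -0.02 (without labelled Hhex-deleted replicate 2) for Cdkn3, and from -1.62 (without labelled Hhex-deleted replicate 2) to -0.33 (without labelled Hhex-deleted replicate 1) for Cdkn1c. By camera the list as a whole was not past the threshold (adjusted p = 0.17), nor was it by fry for one direction (adjusted p = 0.219). Fry's test for change in either direction gave an adjusted p of 1.8e-04. The Cdkn2a call was lost without labelled Hhex-deleted replicate 2 (adjusted p = 0.0502), without wild-type replicate 1 (0.105) and without wild-type replicate 2 (0.123), and that of Cdkn2b was lost whichever library was left out (0.0579 to 0.199).

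Across 14912 tested genes, 221 were higher and 167 lower in the libraries labelled Hhex-deleted. At an unadjusted p under 0.05 there were 1132 and 1228. The higher genes moved further: 100 of them rose at least 4-fold, against 10 that fell at least 4-fold. All 388 had groups that did not overlap, as did 45.5% of all tested genes, where chance gives 33.3%. Of the 388 genes, 20 are absent from the deposited log2 RPKM tables, Cdkn2b among them. Without labelled Hhex-deleted replicate 1 the counts were 366 and 231, of which 307 genes were shared with the full comparison. They fell to 119 higher and 142 lower without wild-type replicate 1, and to 84 and 40 without wild-type replicate 2. DESeq2 called 493 and 508 genes, and limma-voom 123 and 79.

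Among genes past the test with a mean of at least 1 CPM, the largest increases were in genes that were nearly silent in wild-type cells. Cabp1, a calcium-binding protein gene, had 160 reads over both libraries against 1, a ratio of 151 (95% interval 26.7 to 6000), and Wscd1 had 247 against 2, a ratio of 117 (95% interval 31.9 to 967). Irs1, an adaptor of the insulin receptor, stood at 7.06 and 7.23 CPM against 0.0715 ± 0.00209 CPM (SD, n = 2), a log2 fold change of 6.56 ± 0.33 (SE, edgeR adjusted p = 0.00212). Lef1, a transcription factor of the Wnt pathway, rose by 4.7 ± 0.36 (SE) on the log2 scale, Tnfrsf19 by 4.56 ± 0.39 and the growth factor gene Bmp4 by 4.26 ± 0.59. Spats2l (6.66), 2610019F03Rik (5.43) and Tmem198 (4.94) completed the group together with Airn (4.52), an RNA antisense to Igf2r, whose reads cannot be assigned between the overlapping genes without strand. The calls of Spats2l and Bmp4 were lost without wild-type replicate 1 (adjusted p = 0.24 and 0.0704) and without wild-type replicate 2 (0.341 and 0.132).

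Among genes past the test with a mean of at least 1 CPM, Ccnd1, a D-type cyclin that drives entry into S phase, fell most. Ccnd1 stood at 2.91 and 5.64 CPM against 31.2 ± 1.01 CPM (SD, n = 2) in wild-type. Its log2 fold change was -2.87 ± 0.32 (SE, edgeR adjusted p = 0.0226). Serpinf1, a secreted protein of the serpin family, fell by 2.3 ± 0.09 (SE, edgeR adjusted p = 0.00183) on the log2 scale. Endou (-2.48), Wdr65 (-2.42), Phldb2 (-2.27) and the imprinted RNA Meg3 (-2) were also lower, as was an unnamed gene with Entrez identifier 100503188 (-1.99). Igkv5-43 (-2.57) belongs to a family of similar gene segments, and Tnfsf13 (-2.13) and 2010012P19Rik (-2.04) lie in overlapping annotations, so their reads may be shared with neighbours or relatives. The call of Ccnd1 was lost without wild-type replicate 1 (adjusted p = 0.0679) and without wild-type replicate 2 (0.111). Of the other 9 of these 10 largest decreases only Serpinf1 kept its call whichever library was left out. The rest lost theirs without wild-type replicate 2 (adjusted p = 0.0818 for Wdr65 to 0.255 for Meg3), and some also without wild-type replicate 1 (0.0525 for Entrez identifier 100503188, 0.0681 for Igkv5-43, 0.052 for Tnfsf13, 0.0671 for Meg3), without labelled Hhex-deleted replicate 2 (0.0502 for Igkv5-43, 0.0805 for Tnfsf13, 0.175 for 2010012P19Rik, 0.0907 for Meg3) or without labelled Hhex-deleted replicate 1 (0.13 for 2010012P19Rik, 0.0649 for Meg3).

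**Figure D1:**
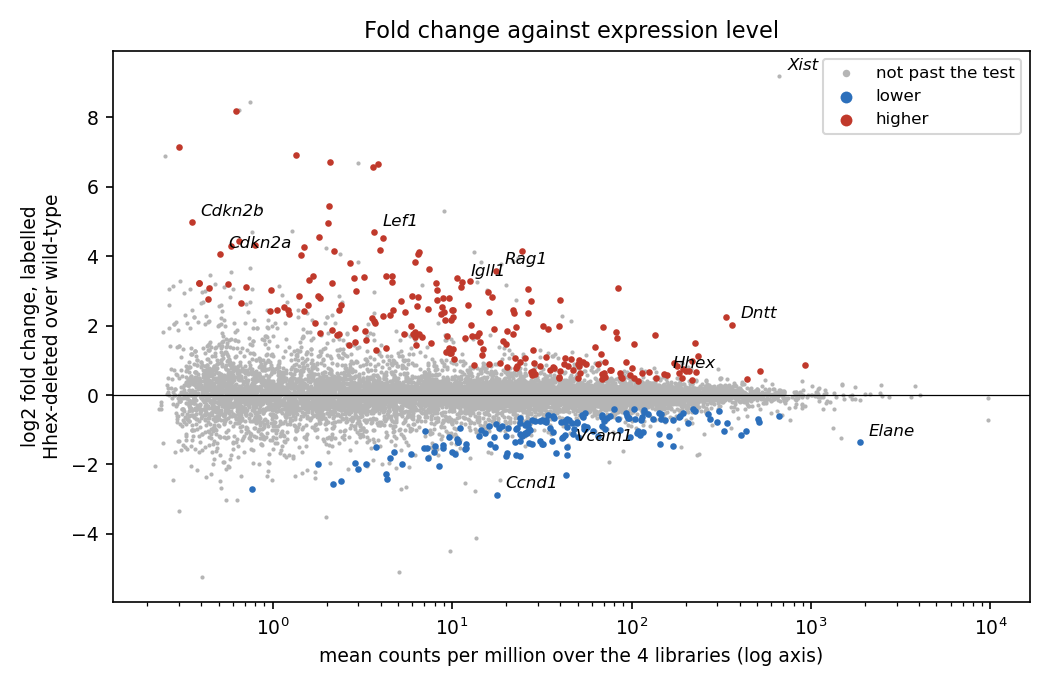
Each point is one of 14912 tested genes, with the mean CPM over the 4 libraries on a log axis and the log2 fold change of labelled Hhex-deleted over wild-type libraries on the other axis; red marks the 221 genes past the test as higher, blue the 167 lower, grey the rest. Increases reach further from 0 than decreases, with Cdkn2a at 4.06 and Ccnd1 at -2.87; Xist is grey because a single library carries it.

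Of 17 measured B lineage genes 9 were higher and none lower (10 higher adjusted over the list alone), with a list median of 2.46 on the log2 scale. That median does not describe all members, and it was 1.8 over 18 genes with DESeq2. The list holds 7 mature B cell genes, a set put together after values were seen. Their median was 0.37 (range -0.16 to 1.12), and none passed edgeR's test. Igll1 and Vpreb1, which encode the surrogate light chain of B cell precursors, rose by 3.25 ± 0.19 and 2.78 ± 0.2 (SE), and Vpreb3 by 3.64 ± 0.26, with edgeR adjusted p-values of 0.00369, 0.00434 and 0.00434. Igll1 stood at 18.6 and 22.5 CPM against 2.16 ± 0.215 CPM (SD, n = 2). Without labelled Hhex-deleted replicate 1, the library with female markers, 9 B lineage genes were higher, and without any one of the other libraries 7. Reads of Vpreb1 can be shared with its near copy Vpreb2. Of 23 lymphoid priming genes 5 were higher and none lower (12 higher adjusted over the list alone), with a median of 0.56. Of these 12 were higher without labelled Hhex-deleted replicate 1, 4 without labelled Hhex-deleted replicate 2 (median 0.29), 3 without wild-type replicate 1, where 1 was lower, and 4 without wild-type replicate 2. Rag1, which cuts antigen receptor genes for their assembly, rose by 3.58 ± 0.24, the interleukin receptor gene Il7r by 2.98 ± 0.18, the adaptor gene Blnk by 2.46 ± 0.22 and the DNA polymerase gene Dntt by 2.03 ± 0.2, the last from 144 ± 12.7 to 475 and 698 CPM. Camera gave adjusted p-values of 1.8e-10 for B lineage and 3.6e-09 for lymphoid priming genes, and an adjusted p of 0.671 for each with an estimated correlation. The call of Dntt was lost without wild-type replicate 1 (adjusted p = 0.084) and without wild-type replicate 2 (0.132).

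Of 14 plasma cell and immunoglobulin genes 1 was higher, Sdc1 (2.45 ± 0.23 SE, edgeR adjusted p = 0.0131), and 2010001M09Rik (Mzb1 in the list) stood at 1.78 without passing the test. Adjusted over the list alone 3 were higher. The list's median was -0.12, its mean 0.09 and its camera direction up (adjusted p = 0.634), and the median ran from -0.52 without labelled Hhex-deleted replicate 2 to 0.76 without wild-type replicate 2. Of these genes 3 were higher without labelled Hhex-deleted replicate 1 and 0 without wild-type replicate 1 or wild-type replicate 2, and 1 was lower without labelled Hhex-deleted replicate 2 or wild-type replicate 1. None of 10 MHC class II genes passed edgeR's test, with 2 higher at an unadjusted p under 0.05, H2-Ob (0.68) and H2-Oa (0.46), 1 called by DESeq2 and 0 by limma-voom. That list's median was -0.11 and its camera direction up (adjusted p = 0.947). The median was 0.43 with 1 gene higher without labelled Hhex-deleted replicate 1, and -0.6 with 4 genes lower without labelled Hhex-deleted replicate 2. Of 23 T and natural killer lineage genes 3 were higher and 1 lower (4 and 2 adjusted over the list alone), with a median of 0.12 (from -0.15 without labelled Hhex-deleted replicate 2 to 0.78 without labelled Hhex-deleted replicate 1) and a camera adjusted p of 0.173. These were Lef1 (above), Lat, an adaptor of the T cell receptor that mast cells and platelets also use (1.64 ± 0.1 SE, edgeR adjusted p = 0.00407), Zap70, a kinase of the same receptor (2.59 ± 0.39 SE, edgeR adjusted p = 0.0305), and Nkg7 (-0.56 ± 0.09 SE, edgeR adjusted p = 0.0421), which the list of granulocyte monocyte progenitor genes also holds. The call of Sdc1 was lost without wild-type replicate 1 (adjusted p = 0.0501) and without wild-type replicate 2 (0.0939), that of Zap70 without labelled Hhex-deleted replicate 2 (0.0502), without wild-type replicate 1 (0.078) and without wild-type replicate 2 (0.148), and that of Nkg7 whichever library was left out (0.0594 to 0.244).

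Of 17 measured mast cell, basophil and eosinophil genes 11 rose and none fell (14 higher adjusted over the list alone), with a median of 1.71. Cpa3, a protease of mast cell granules, rose from 116 ± 13.6 to 578 and 533 CPM, a log2 fold change of 2.26 ± 0.11 (SE, edgeR adjusted p = 0.0021). Ms4a2, a chain of the high-affinity receptor for immunoglobulin E, rose by 2.71 ± 0.12, and the basophil proteases Mcpt8 and Prss34 by 1.81 ± 0.08 and 1.96 ± 0.1 (edgeR adjusted p = 0.00183, 0.00183 and 0.0021). Of 18 granulocyte monocyte progenitor genes 8 fell and none rose (14 lower adjusted over the list alone), with a median of -0.83. Elane, the neutrophil elastase gene, fell from 2700 ± 596 to 1075 and 1048 CPM, a log2 fold change of -1.35 ± 0.16 (SE, edgeR adjusted p = 0.0226). Also lower were Ly6c2, whose near copy Ly6c1 can share its reads, with a log2 fold change of -1.03 ± 0.09 (SE), Clec12a with -1.04 ± 0.13 and Igsf6 with -1.13 ± 0.14 (edgeR adjusted p = 0.00865, 0.0204 and 0.0231). In the mast cell list 12 genes were higher without labelled Hhex-deleted replicate 1, 11 without labelled Hhex-deleted replicate 2, 7 without wild-type replicate 1 and 8 without wild-type replicate 2. In the progenitor list 8 were lower without labelled Hhex-deleted replicate 1, 1 without labelled Hhex-deleted replicate 2, 8 without wild-type replicate 1 and 5 without wild-type replicate 2. Camera gave adjusted p-values of 9.6e-17 and 4.7e-14 for the 2 lists, and an adjusted p of 0.671 for each with an estimated correlation. The calls of Elane and Clec12a were lost without labelled Hhex-deleted replicate 1 (adjusted p = 0.175 and 0.0686) and without labelled Hhex-deleted replicate 2 (0.25 and 0.072), and that of Igsf6 without the latter (0.0927).

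**Figure D2:**
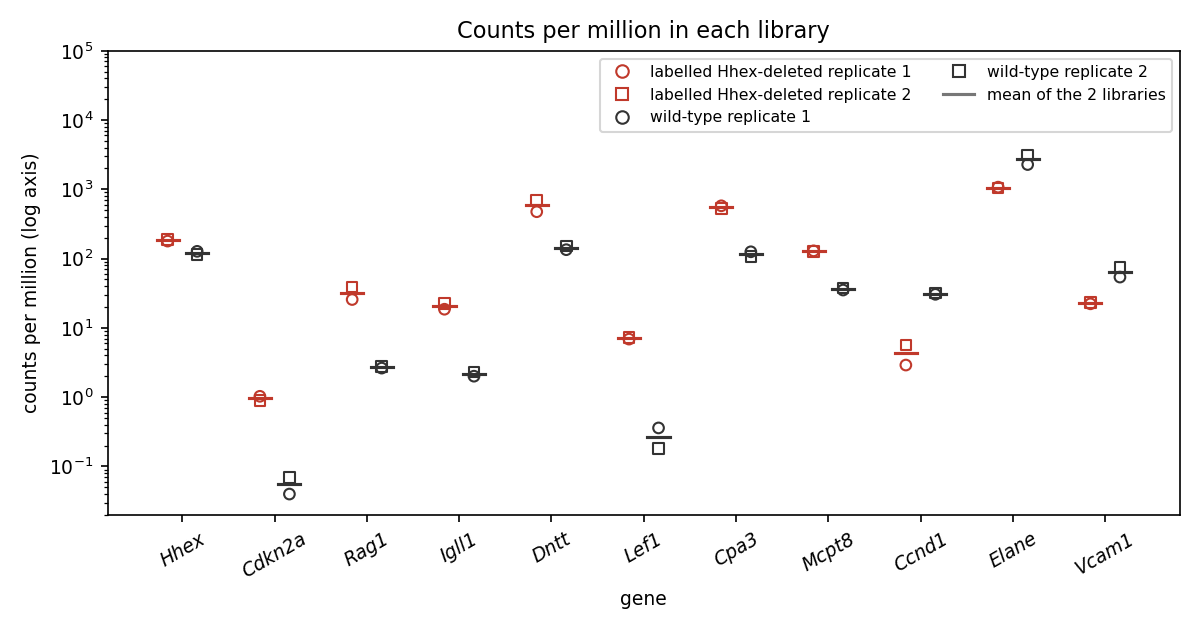
CPM in each library on a log axis for 11 named genes, with red symbols for libraries labelled Hhex-deleted, black for wild-type, circles for replicate 1, squares for replicate 2 and bars for group means (n = 2). Elane falls from a mean of 2700 CPM to 1075 and 1048 CPM, and Rag1 stands at 25.7 and 39.1 CPM against a wild-type mean of 2.71 CPM.

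Among mature myeloid genes, 3 of 23 monocyte, macrophage and dendritic cell genes were higher and 1 lower (6 and 5 adjusted over the list alone). The counts were 4 and 3 without labelled Hhex-deleted replicate 1, 4 and 2 without labelled Hhex-deleted replicate 2, and 0 and 1 without wild-type replicate 2. C1qa, C1qb and C1qc, which encode the subunits of complement component C1q, rose by 2.27 ± 0.3, 2.08 ± 0.25 and 2.22 ± 0.23 (SE), from wild-type means of 1.42, 1.42 and 1.27 CPM (edgeR adjusted p = 0.0227, 0.019 and 0.0132). Vcam1, an adhesion molecule, fell by 1.5 ± 0.17 (SE, edgeR adjusted p = 0.018) on the log2 scale, from 64.5 ± 14.7 to 22.3 and 23.4 CPM. The list's median was -0.2 (-0.03 without labelled Hhex-deleted replicate 1, -0.32 without wild-type replicate 1 and -0.02 without wild-type replicate 2) and its mean 0.17, with camera's direction down (adjusted p = 0.947) and fry's up (adjusted p = 0.648). Of 17 mature neutrophil genes 1 was higher, Mmp9 (1.92 ± 0.27 SE, edgeR adjusted p = 0.0255), with 1 higher and 2 lower adjusted over the list alone, Itgam at -0.67, a list median of -0.94 and a camera adjusted p of 0.0622 (0.0268 with no low-count filter). That median ran from -2.36 without labelled Hhex-deleted replicate 2 to -0.25 without wild-type replicate 2, with -0.29 without labelled Hhex-deleted replicate 1. The calls of the C1q genes were lost without wild-type replicate 2 (adjusted p = 0.0713 to 0.0994) and that of Mmp9 without wild-type replicate 1 (0.107) and without wild-type replicate 2 (0.0987). The call of Vcam1 was lost without labelled Hhex-deleted replicate 1 (adjusted p = 0.0824) and without labelled Hhex-deleted replicate 2 (0.104).

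Of 30 long-term haematopoietic stem cell genes 2 were higher and 1 lower (4 and 3 adjusted over the list alone), with a median of 0.02 and camera's direction down (adjusted p = 0.947). Fry's adjusted p for this list was 0.954 for one direction and 0.0019 for change in either direction. The counts were 4 and 1 without labelled Hhex-deleted replicate 1, 1 and 2 without labelled Hhex-deleted replicate 2, and 1 and 0 without wild-type replicate 1 or wild-type replicate 2. Neo1, a receptor for netrins, rose from 1.83 ± 0.528 to 9.59 and 12.1 CPM, a log2 fold change of 2.56 ± 0.27 (SE, edgeR adjusted p = 0.0139). Mllt3, a chromatin reader, rose by 0.68 ± 0.11 (SE, edgeR adjusted p = 0.0361) and the receptor gene Tie1 fell by 0.68 ± 0.09 (SE, edgeR adjusted p = 0.0227) on the log2 scale, with Robo4 at -0.89 and not past the test. Of 24 erythroid genes 2 were higher and none lower, both counts the same adjusted over the list alone, with a median of 0.54. They were the transcription factor gene Gfi1b (0.94 ± 0.15 SE, edgeR adjusted p = 0.0421) and the carbonic anhydrase gene Car2 (0.68 ± 0.12 SE, edgeR adjusted p = 0.049), with Spna1 at 0.73 and Rhag at 0.71 not past the test. Camera called the erythroid list (adjusted p = 1.4e-04), with an adjusted p of 0.671 with an estimated correlation. Erythroid genes past edgeR's test as higher numbered 1 without labelled Hhex-deleted replicate 1 (median 0.27), 5 without labelled Hhex-deleted replicate 2 (median 0.94), and 0 without wild-type replicate 1 or wild-type replicate 2. Of 32 interferon-stimulated genes 3 were higher and 1 lower, also adjusted over the list alone, with a median of 0.29. Usp18, which restrains interferon receptor signalling, rose by 1.2 ± 0.2 (SE), Rtp4 by 0.96 ± 0.12 and Irgm1 by 0.51 ± 0.07, and Gbp3, a guanylate-binding protein, fell by 0.82 ± 0.08 (SE) on the log2 scale (edgeR adjusted p = 0.042, 0.019, 0.0291 and 0.0128). Camera called the interferon list (adjusted p = 0.00122), with an adjusted p of 0.671 with an estimated correlation, and the call was lost without labelled Hhex-deleted replicate 1 (0.0796) and without wild-type replicate 2 (0.0515). Interferon-stimulated genes numbered 4 higher and 1 lower without labelled Hhex-deleted replicate 1 (median 0.09), 2 and 1 without labelled Hhex-deleted replicate 2, 0 and 1 without wild-type replicate 1 (median 0.44), and 0 and 0 without wild-type replicate 2. Of the single genes past the test here, only Neo1 kept its call whichever library was left out. Without wild-type replicate 2 the adjusted p was 0.0566 for Tie1, 0.168 for Mllt3, 0.191 for Gfi1b, 0.203 for Car2 and Usp18, 0.0599 for Gbp3, 0.0982 for Rtp4 and 0.149 for Irgm1. Without wild-type replicate 1 it was 0.0884 for Tie1, 0.0658 for Mllt3, 0.0853 for Gfi1b and Usp18, 0.0525 for Car2, 0.052 for Rtp4 and 0.171 for Irgm1. Without labelled Hhex-deleted replicate 2 it was 0.0761 for Mllt3, 0.124 for Car2 and 0.0558 for Irgm1, and without labelled Hhex-deleted replicate 1 it was 0.0542 for Car2 and 0.0682 for Usp18.

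Several fixed lists, those of cell cycle phases and ribosomes among them, had no member past edgeR's test. None of 27 S phase genes (median 0.04, Rrm2 at -0.22 and Cdt1 at -0.16, camera adjusted p = 0.534) and none of 28 G2 and M phase genes (median -0.04, Aurkb and Cdca8 at -0.23, camera adjusted p = 0.634) was called. The same was found for 20 p53 target genes (median 0, Trp53inp1 at 0.89 and Ccng1 at 0.25, camera adjusted p = 0.3), 27 Polycomb group genes (median 0.05, Pcgf2 at -0.76 and Phc2 at 0.27, camera adjusted p = 0.634) and 17 Hox genes and cofactors (median 0.2, Meis1 at 0.43, camera adjusted p = 0.3). It was also found for 38 cytosolic ribosomal protein genes (median -0.02, Rpl27 at -0.25, camera adjusted p = 0.753) and 26 ribosome biogenesis and Myc target genes (median -0.02, Myc at 0.29 and Polr1a at 0.18, camera adjusted p = 0.947). The 22 megakaryocyte and platelet genes had a median of 0.2, with Itga2b at 0.48 and Gp5 at 0.42 (camera adjusted p = 0.239; median 0.04 and 1 gene lower without labelled Hhex-deleted replicate 1, 0.43 and 2 genes higher without labelled Hhex-deleted replicate 2, 0.09 without wild-type replicate 2), and the 11 stromal and endothelial genes a median of 0.69, with Cdh5 at 2.67 and Stab2 at 1.44 (camera adjusted p = 0.122; median -0.04 without labelled Hhex-deleted replicate 1, and 1 gene higher and 1 lower without labelled Hhex-deleted replicate 2). The 7 measured genes near Hhex had a camera adjusted p of 0.947. The 27 immediate early and heat shock genes had a median of -0.66, with Fosl2 at -0.75 and Hsph1 at -0.28 (camera adjusted p = 0.122). That median was -1.78 without labelled Hhex-deleted replicate 1, 0.01 without labelled Hhex-deleted replicate 2, 1.7 without wild-type replicate 1 and -1.28 without wild-type replicate 2, and 1 gene was lower without labelled Hhex-deleted replicate 2 or wild-type replicate 2. With the replicate number as a block, 3 immediate early and heat shock genes were lower by edgeR's test. Camera called 2 lists of small changes as lower, glycolysis genes (20 genes, median -0.16, Pkm2 at -0.4, Slc16a3 at -1.06, Pgam1 at -0.49, Gpi1 at -0.41, adjusted p = 0.0032) and oxidative phosphorylation genes (35 genes, median -0.08, Ndufa4 at 0.27, Cox5a and Ndufb8 at -0.25, Uqcrc1 at -0.26, adjusted p = 0.00826). With an estimated correlation the adjusted p was 0.671 for glycolysis and 0.979 for oxidative phosphorylation genes. At an unadjusted p under 0.05, 1 glycolysis gene was higher and 9 lower, and DESeq2 called 5 as lower. By edgeR's test 2 glycolysis genes were lower and 0 oxidative phosphorylation genes without labelled Hhex-deleted replicate 1 (medians -0.16 and -0.18), and 1 and 0 without wild-type replicate 1. The median of oxidative phosphorylation genes was 0 without labelled Hhex-deleted replicate 2. The p53 target list had 2 genes higher without labelled Hhex-deleted replicate 1, and a median of 0.25 without wild-type replicate 1, and the Hox list a median of -0.01 without labelled Hhex-deleted replicate 2. Adjusted over the list alone, 6 glycolysis genes were lower and 1 stromal and endothelial gene was higher.

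The 14 lists without a member past edgeR's test had 315 measured entries, in which a gene of more than one list, such as Kif11, counts once per list. Of these entries 18 were higher and 17 lower at an unadjusted p under 0.05, DESeq2 called 7 and 6, and limma-voom called 0. The glycolysis list held 9 of these 17 and 5 of these 6 lower entries. Camera with the preset correlation called 8 of 26 lists. With an estimated correlation it called 0, the smallest adjusted p being 0.671, and fry called 0 for one direction and 9 for change in either direction. The median of MHC class II genes was 0.43 without labelled Hhex-deleted replicate 1 and -0.6 without labelled Hhex-deleted replicate 2. Its camera calls in those 2 fits, given next, therefore have opposite directions. Some lists not past camera with all libraries passed it with a library left out. Without labelled Hhex-deleted replicate 1 these were the lists of G2 and M phase (adjusted p = 0.0342), Hox (0.0313), T and natural killer lineage (7.6e-04), MHC class II (0.00134), immediate early and heat shock (0.00145), ribosomal protein (0.00796) and ribosome biogenesis genes (0.0342). Without labelled Hhex-deleted replicate 2 they were mature neutrophil (5.4e-05), MHC class II (4.0e-04) and megakaryocyte genes (4.0e-04), without wild-type replicate 1 p53 target (0.031) and mature neutrophil genes (2.1e-05), and without wild-type replicate 2 immediate early and heat shock genes (1.2e-16). The oxidative phosphorylation call was lost without labelled Hhex-deleted replicate 2 (adjusted p = 0.957) and without wild-type replicate 1 (0.138).

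**Figure D3:**
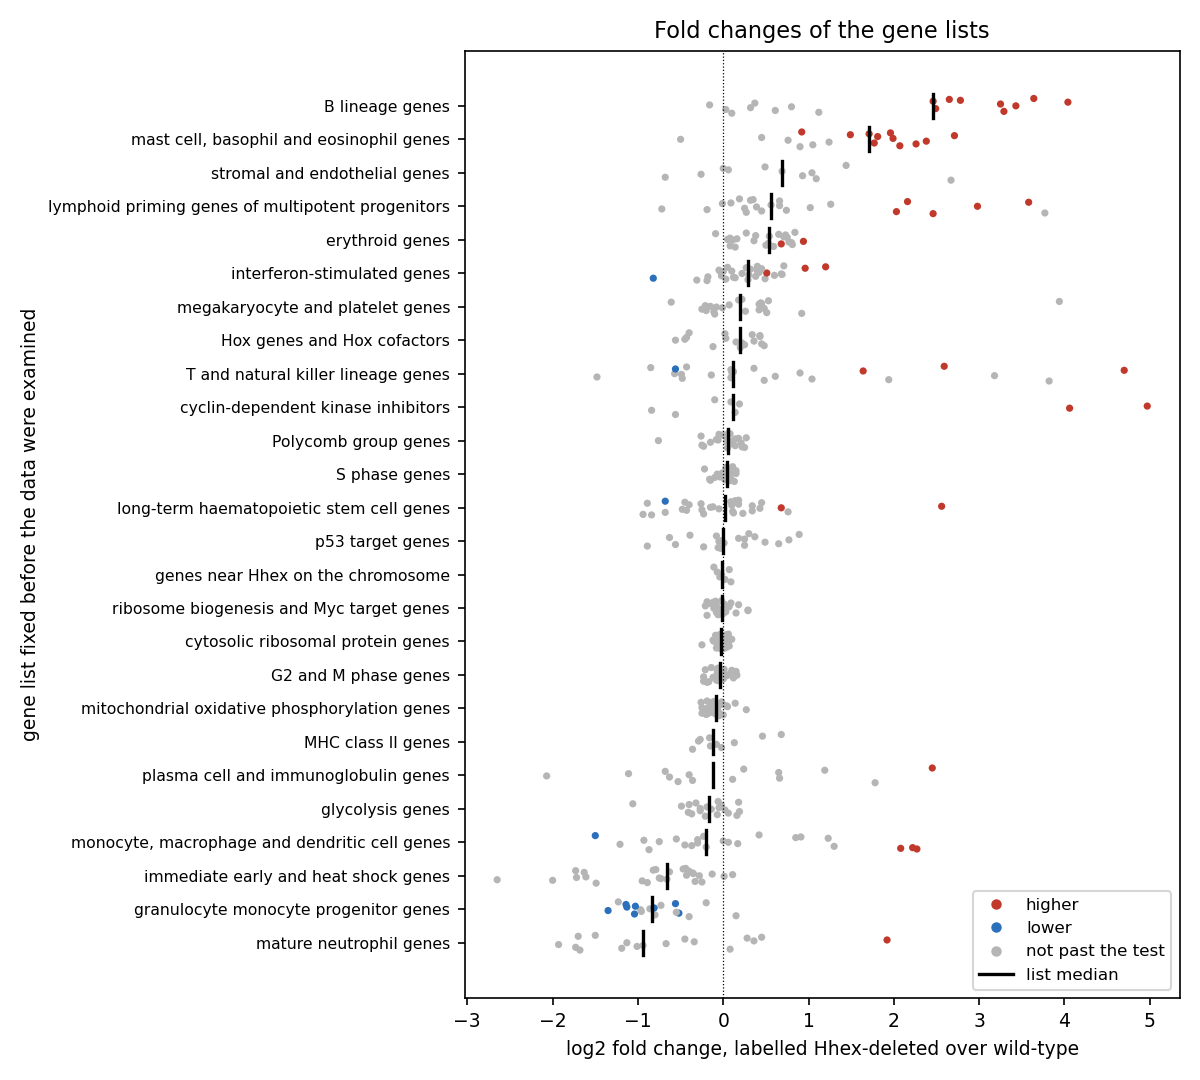
Log2 fold changes of labelled Hhex-deleted over wild-type libraries for the measured members of 26 gene lists, one row per list in order of the median (black bar); red and blue points passed the test as higher or lower and grey points did not. The B lineage list has the highest median (2.46) and mature neutrophil genes the lowest (-0.94), and cell cycle and ribosomal lists lie near 0.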

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

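The fit on deposited log2 RPKM values and that without X- and Y-linked genes were chosen after seeing the data; the rest were planned. All 388 genes past the test kept their direction wherever they were tested, in every alternative. Since their groups do not overlap, refits of the same libraries could hardly turn a sign, so this is no separate support. The 221 higher and 167 lower genes became 493 and 508 with DESeq2 (382 shared) and 123 and 79 with limma-voom (201 shared). The stricter filter gave 147 higher genes and no low-count filter 272 lower. Library totals alone gave 86 lower, the fit without robust dispersion 99 lower, and the deposited log2 RPKM values 34 and 6. The cause of these and the other changes below was not tested. Without X- and Y-linked genes they were 222 and 171. Leaving out 1 library, whose lone partner is then assumed to vary like the other group, gave 84 to 366 higher and 40 to 231 lower genes. Hhex stayed between 0.53 and 0.67 and Cdkn2a between 3.70 and 4.57 in these fits, with adjusted p-values of 0.03 to 0.148 and 0.0481 to 0.123; on log2 RPKM values they were 0.62 and 3.63 (adjusted p = 0.0719 for both). Named genes with few reads, Cdkn2a, Cdkn2b, Irs1 and Lef1 among them, were removed by the stricter filter and have no value there, nor has Cdkn2b with DESeq2 or on log2 RPKM values. Of 57 named genes past the test, 23 kept their call whichever library was left out. Camera called 8 lists, 0 with an estimated correlation, 0 with fry, and 8 to 14 with a library left out.

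The replicate numbers are shared by the groups, but no label says that they pair samples. On principal component 2 of log2 CPM, an axis that held 30.3% of the variance, replicates numbered 1 and 2 lay apart in both groups. Their positions were 24.3 and -29.8 in the libraries labelled Hhex-deleted and 22.6 and -17.1 in wild-type. Differences between replicates 1 and 2 correlated across genes between the groups (0.33 over tested genes, 0.94 over immediate early genes). With the replicate number as a block there were 185 higher and 130 lower genes, 245 of them shared with the unblocked fit, Hhex at 0.60 (adjusted p = 0.0518), Cdkn2a at 4.06 (adjusted p = 0.0524), Cdkn2b at 4.96 (adjusted p = 0.0764), so 0 of 8 cyclin-dependent kinase inhibitors were past the test with edgeR, and 11 lists. The lists added were mature neutrophil (camera adjusted p = 0.00379), megakaryocyte (0.0493) and immediate early genes (1.3e-09). In the last list 3 genes were lower by edgeR's test with the block (median -0.54). Of the 10 largest decreases, Phldb2 (edgeR adjusted p = 0.057), Tnfsf13 (0.0809), Meg3 (0.0613), the Igkv gene (0.0747) and the Rik gene (0.0516) lost their calls. Mllt3 (0.0726), Zap70 (0.0602), Igsf6 (0.0559) and Car2 (0.094) also lost theirs.

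Reversals of sign were seen in results not past the test with all libraries, and the MHC class II list was past it in the other direction without labelled Hhex-deleted replicate 2 (4.0e-04). Cpeb3 was -0.01 after thinning and Ide 0.00 with library totals. With a library left out, ranges were -1.2 to 0.64 for Cdkn1a, -0.01 to 0.2 for Cdkn2d, -0.18 to 0.2 for Cpeb3, -0.06 to 0.22 for Marchf5, -0.04 to 0.00 for Ide, -0.09 to 0.02 for Exoc6 and -0.64 to 0.28 for Myof. They were -8.53 to 0.1 for Ddx3y, -10.27 to 0.25 for Eif2s3y, -8.72 to 0.15 for Kdm5d and -8.16 to 0.26 for Uty, which follow the library of the other sex. For lists whose direction turned with a library left out, ranges of camera adjusted p-values cover all such fits, turned or not. These ranges were 0.031 to 0.711 (p53), 0.0693 to 0.83 (S phase), 0.0342 to 0.83 (G2 and M phase) and 0.169 to 0.72 (Polycomb). Further ranges were 0.285 to 0.899 (stem cell), 0.0796 to 0.957 (plasma cell), 4.0e-04 to 0.83 (MHC class II) and 4.0e-04 to 0.839 (megakaryocyte). The last were 1.2e-16 to 0.943 (immediate early), 0.00796 to 0.663 (ribosomal protein), 0.0342 to 0.354 (ribosome biogenesis) and 0.791 to 0.957 (genes near Hhex). Each of these values under 0.05 came from a fit that kept the main direction, except the 4.0e-04 of MHC class II genes. The monocyte list turned to up with fry (0.648). Counts from per-sample files were not run, since those files hold log2 values. Genes with few wild-type reads, such as Cdkn2a and Cdkn2b, are limited by depth to wide ratio intervals.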

Other observations

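The tests in this part were chosen after the result was seen, except that of the B lineage and mast cell lists without the library of the other sex, whose limits were written before its values were seen. The gene sets named here and not in the fixed lists were also put together after values were seen.

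Some genes outside the fixed lists are given here as values, and no enrichment of these groups was tested. The Hippo pathway coactivator genes Yap1 and Wwtr1 rose by 3.81 ± 0.58 and 4.11 ± 0.4 (SE) on the log2 scale (edgeR adjusted p = 0.039 and 0.0128), and their DNA-binding partner Tead1 had 74 reads over both libraries labelled Hhex-deleted and 0 in wild-type, at least 23.3-fold higher against a floor of 3 counts over the group. The upstream kinase genes Lats1, Lats2, Stk3 and Stk4 stood at 0, 0.18, 0.01 and 0.07, Tead2 at -1.19 (adjusted p = 0.0554) and Tead3 at -1.03, none past the test. Of 14 tested pathway genes 3 were higher and 0 lower by edgeR, with a median of 0.01. The target genes Ccn1 and Ccn2 had at most 11 reads in any library and were not tested. Axl (1.91 ± 0.21 SE), Siglec1 (2.32 ± 0.38) and Hmox1 (1.33 ± 0.13), which tissue macrophages express, were picked from the genes past the test as higher, while Csf1r, a receptor of that lineage, stood at -1.21 (adjusted p = 0.419) and Vcam1 was lower. Immediate early genes stood higher in the replicates numbered 1 than in those numbered 2, by a median of 2.07 on the log2 scale in the libraries labelled Hhex-deleted and 2.86 in wild-type. Nr4a1 had 213 and 712 CPM in the replicates numbered 1 and 2.82 and 4.48 CPM in those numbered 2.

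Of the B lineage and mast cell, basophil and eosinophil lists 9 of 17 and 11 of 17 genes were higher, and of the granulocyte monocyte progenitor list 8 of 18 were lower (1 without labelled Hhex-deleted replicate 2), with a camera adjusted p of 0.671 for each list with an estimated correlation and none past fry's test for one direction (fry's test for either direction gave adjusted p-values of 0.0335, 0.00665 and 0.0527). Reads from mature B or plasma cells would not bring Igll1, Vpreb1, Rag1, Rag2 and Dntt, whose median log2 fold change was 2.78. All 5 were already past the test as higher, so this median was fixed by their choice and speaks only to these genes. A set of 7 abundant transcripts of those cells, Igkc and Ighm among them, had a median of -0.36. They summed to 883 and 1137 CPM against 1209 and 2027 in wild-type. A first test on 7 mature B cell genes (median 0.37) was replaced after its value was seen, because only 3 of them reached 1 CPM in wild-type. A low wild-type level would not by itself hide added reads of mature B cells. These genes ran from -0.16 to 1.12 on the log2 scale, and none passed edgeR's test. A lower share of cells that express granulocyte monocyte progenitor genes would raise every other lineage alike. The B lineage median exceeded the megakaryocyte median by 2.26 (bootstrap over genes, 95% interval 0.19 to 2.95). With a library left out the medians were 2.07 to 2.74 for B lineage and 0.04 to 0.43 for megakaryocyte genes. The interval treats genes as independent, although the estimated correlation was 0.68 and 0.31 in these lists. It holds no spread between libraries, so the interval alone does not decide the question. Other lists did not rise alike. Their medians were 1.71 for mast cell, basophil and eosinophil genes and 0.54 for erythroid genes. They were 0.12 for T and natural killer lineage genes and 0.02 for stem cell genes. With a library left out the mast cell median stayed between 1.33 and 1.82. For these lists the unequal medians argue against an equal rise of every other lineage. Without the library of the other sex the medians were 2.74, 1.33 and -0.95 for the B lineage, mast cell and progenitor lists, so its sex alone does not account for them. B cell precursors inside the sort gate, which the lineage-negative gate removes where it includes B cell markers, cannot be told apart from an effect of the labelled deletion within LSK cells, since the 10 of 10 early B cell genes that rose (10 in the fixed lists, 8 at 1 CPM or more in wild-type) are the pattern's own genes.

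Hhex reads were higher in the libraries labelled Hhex-deleted. A change shared by the genes around Hhex would move its neighbours too, but their median was -0.02 (range -0.11 to 0.09). If the group labels are right, reads from retained exons at an unchanged level would give at most the wild-type count, not 1.51-fold of it. They would then not be the whole source, provided that the rise of Hhex holds. Its call was lost with the replicate number as a block (edgeR adjusted p = 0.0518) and on log2 RPKM values (limma adjusted p = 0.0719). With a library left out the log2 fold change of Hhex ran from 0.53 to 0.67. An exchange of all group labels could give the rise (log2 fold change 0.60 ± 0.09 SE). Cdkn2a, which the series title describes as repressed by Hhex, was 17.9-fold higher in the libraries labelled Hhex-deleted, the direction the labels give, but it is the study's own outcome and no separate check of them, so an exchange cannot be told apart from a regulated rise of the remaining transcript, which was not tested.

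Genes past the test often lay next to genes past the test in the same direction, such as Igll1 with Vpreb1, Chpf with Tmem198 and Obsl1, and Mtap with Cdkn2a and Cdkn2b. Neighbours here are successive tested genes along a chromosome, at any distance, so untested genes can lie between them. There were 28 such adjacent pairs among 14171 placed genes, where 10000 random placements gave a mean of 5.16 and at most 15 (permutation p = 1e-04, one-sided, the smallest they can give). Of these, 14 remained without pairs whose annotations overlap or whose symbols share their first 3 letters, against a mean of 4.25 and at most 13 (permutation p = 1e-04, the smallest they can give), so shared reads of that kind are not the whole source. Transcripts that run on into the next gene, and regulation shared by neighbours, remain open as hypotheses and were not tested.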
